A study of Drosophila melanogaster with 3 samples.

How the data were processed

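The data are chromatin immunoprecipitation sequencing (ChIP-seq) of the forkhead transcription factor foxo in Drosophila melanogaster. The line carries an eGFP exon inserted into an intron of foxo, so that the gene makes a foxo-eGFP fusion, and the precipitation used an antibody against GFP, per the labels. Each library came from whole wandering larvae of both sexes, and sonicated fragments of 200 to 800 bp were selected, per the labels. There were 3 biological replicates, each from its own larval sample, and they form 1 group. No untagged or input library was analysed here, so signal that does not depend on foxo cannot be separated from signal that does.

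The deposited files are peak lists in narrowPeak format, each given on the dm6 and on the dm3 build. For each replicate, and for the 3 replicates pooled, the authors deposited a relaxed list of 30000 peaks and background regions made as input to the irreproducible discovery rate (IDR) procedure. They also deposited 1 optimal list that had passed the IDR threshold, which per the file listings was derived from the 3 replicate lists and the pooled list. Every relaxed list was derived from the library alignments and 1 further file shared by all libraries, per the deposited listings. The labels also name a possible control experiment, for which no peak list was analysed here. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The peak height is the signal value that the authors' peak caller wrote for each peak. It is the authors' own value, its normalization is not given in the sources used here, and it served only to rank peaks within 1 list. The deposited lists also carry a −log10 q-value for each peak. This column was saturated: 91.0% of the optimal dm6 peaks shared its highest value of 4.25, and it was not used for ranking. All 9766 optimal dm6 peaks were found with identical coordinates and signal in the pooled list, where they were the 9766 peaks with the highest signal. Sequencing depth is unknown from peak lists, and intervals on shares cover counting error only. Peaks and genes are sites within the same libraries, not replicates, so p-values over them describe this group of libraries.

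Peak positions were taken as summits (start plus the summit offset) on the arms 2L, 2R, 3L, 3R, 4 and X of dm6. The genome was NCBI Release 6, the same assembly as dm6, and genes came from the Ensembl release 115 annotation of that assembly, with 13945 protein-coding genes and 19607 of their distinct transcription start sites (TSSs). Transposable elements in the annotation were left out. The dm3 lists were used for peak counts and for the replicate comparisons, without annotation, and no coordinate was converted between builds.

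Replicates were compared over their top N peaks by signal, N being the number of optimal peaks on the main arms (9766 on dm6, 9407 on dm3). A peak was shared when the other list had a summit within 100 bp. Chance levels came from 200 circular shifts, each moving all summits of an arm by 1 random offset of at least 10000 bp. Shares have Wilson 95% intervals. Features were assigned to each summit in the order 5' UTR, 3' UTR, coding exon, other exon, intron and intergenic. GC-matched chance levels reweighted the shifted positions to the GC content of the summits in windows of 201 bp. A motif was scored as present when its centre lay within 100 bp of the summit, on either strand, and compared with windows centred 500 bp to the left and to the right. The left window entered a two-sided exact McNemar test, adjusted by Benjamini-Hochberg over the panel of 16 motifs. A GC-matched ratio divided the observed share by the share in flank windows reweighted to the GC content of the summit windows in 20 bins. The forkhead core was also ranked among 210 motifs made by permuting its letters. A gene was called bound when an optimal summit lay within 1000 bp of any of its annotated TSSs. Each of 24 gene lists was compared with all other protein-coding genes by a two-sided Fisher's exact test, adjusted by Benjamini-Hochberg over the lists, and with 10000 random lists matched on decile of gene length. The lists held 756 genes, of which 22 stood in more than 1 list (InR, bmm and Sesn among them). All 12 calls and all motif shares were also computed in the top peaks of each replicate.

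The replicate, promoter, motif and gene list tests, the gene lists, the motif panel and the rule for named genes were fixed before the data were examined. The rule named, first, the genes at the 25 optimal peaks with the highest signal whose summit lay within 1000 bp of a protein-coding TSS and within 100 bp of a top N summit in all 3 replicates, with both genes of a shared 5' region. It named, second, foxo, Thor, InR and bmm whatever their values, and last, up to 4 bound members of each gene list with the highest signal. Alternatives tried were interval overlap or summits within 50 bp, 4883 or all peaks per replicate, dm3, other TSS windows, other motif windows and forms, subsets of peaks, length-matched lists and leaving out each replicate. GC matching, the removal of the X from the gene lists, and the alternatives for arms and for the motif panel were added after the data had been seen. Leaving out a replicate meant using the optimal peaks supported by both others. These were fewer peaks, still called and ranked with all 3 replicates, so a change there need not stem from the replicate left out. With 1 group there was no comparison between groups.

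The procedures were tested on simulated data. With 20.0%, 50.0% and 80.0% of 9766 sites shared, the overlap recovered was 21.1%, 50.8% and 80.4%. The shared summits were moved by much less than the limit of 100 bp, so their recovery followed from the setting. In the data the overlap rose from 61.3% within 50 bp to 74.8% within 100 bp. The simulation does not cover this wider scatter of summits. With random sequence that was AT-rich at 9766 simulated summits and no core implanted, the raw ratio of the forkhead core was 1.62 and the GC-matched ratio 1.01. With the core implanted at 10% of the simulated summits, the GC-matched ratio was 1.21. In 50 simulated runs on the 13945 genes, with binding raised to 70% in 6 lists, 79.7% of the changed lists and 0.667% of the unchanged lists were called. All unchanged genes had the same simulated binding rate, whatever their length, and only larger lists were changed. These figures therefore do not cover the effect of gene length in the data, or the smallest lists. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.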

Results

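Binding of foxo, the forkhead transcription factor that acts downstream of insulin signalling, was mapped in whole wandering larvae of Drosophila melanogaster through an eGFP tag on the endogenous gene. The data comprise 3 biological replicates of 1 group, with 30000 deposited peaks and background regions each, and 1 optimal list of 9766 peaks on dm6 that passed the authors' reproducibility threshold. The median width of the optimal peaks was 460 bp. Their signal, the authors' peak height, ranged from 150.7 to 10606 with a median of 321. Sequencing depth per library is unknown from these lists. The design gives no second group, so the comparisons are between replicates and between peaks and the genome.

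The replicates placed most of their strongest peaks at the same sites. Of the top 9766 peaks, replicates 1 and 2 shared 77.2%, replicates 1 and 3 shared 74.0%, and replicates 2 and 3 shared 73.1%, with summits within 100 bp (mean 74.8% ± 2.13, SD over 3 pairs). Summits shifted at random shared 1.49% on average and at most 2.04%. The peak above Ugalt, a UDP-galactose transporter gene on the X, ranked 1, 1 and 3 in replicates 1, 2 and 3, and the peak in an intron of ush ranked 3, 2 and 1. Across optimal peaks, which are not independent replicates, the rank correlation of signal between replicates was 0.827 ± 0.0188 (Spearman's rho, SD over 3 pairs). It covers only the 8847 to 9016 optimal peaks with a summit within 100 bp in both replicates of a pair. Of the optimal peaks, 85.8% were among the top peaks of replicate 1, 86.4% of replicate 2 and 80.5% of replicate 3. The optimal peaks are the highest of the list pooled from these same libraries, so part of this agreement is built in. The share found in all 3 was 65.2% (Wilson 95% interval 64.2 to 66.1). It was 98.8% in the highest decile of signal and 1.74% in the lowest, while 87.8% of the optimal peaks had a summit within 100 bp somewhere in all 3 full lists. The lowest optimal peaks lie near the cut of 9766 peaks applied to each replicate, so part of this fall follows from the cut.

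**Figure D1:**
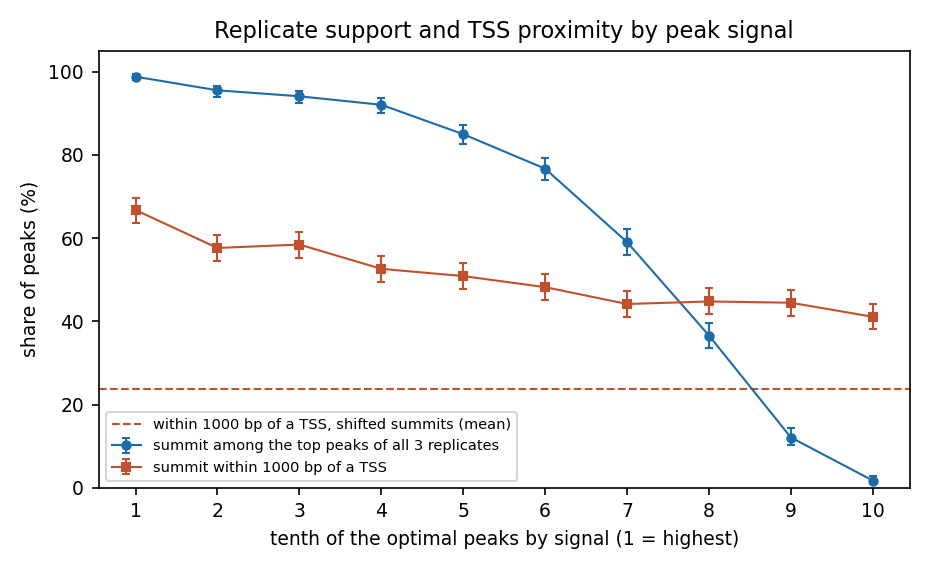
Share of the optimal peaks (vertical axis, %) by decile of signal (horizontal axis, 1 being the highest), with Wilson 95% intervals; circles give peaks with a summit among the top peaks of all 3 replicates, squares give peaks within 1000 bp of a TSS, and the dashed line is the mean of shifted summits for the latter. Support in all 3 replicates falls from 98.8% to 1.74%, whereas TSS proximity falls from 66.7% to 41.1% and stays above the shifted level of 23.6%.

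Peak summits gathered just upstream of transcription start sites and were nearly missing from coding sequence. A TSS lay within 1000 bp of 4971 of the 9766 optimal summits (50.9%, Wilson 95% interval 49.9 to 51.9), against 23.6% on average and at most 25.9% for 200 sets of shifted summits. In the replicates' own top peaks this share was 52.3% ± 2.63 (SD, n = 3). Of the 4576 summits near a protein-coding TSS, 72.9% lay upstream of the nearest one (42.6% of shifted summits), with a median position of -89 bp. The 100 bp directly upstream of the TSS held 1182 summits against 129 on average for shifted sets. From 200 to 300 bp downstream there were 50, against 122. TSSs on both strands lay within 1000 bp of 33.2% of these summits (31.9 to 34.6), against 16.5% of the shifted ones.

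Introns held 50.5% of the optimal summits, intergenic sequence 36.9% and 5' UTRs 8.08%. Coding exons held 39 summits, or 0.399% (0.292 to 0.545), against 16.0% of shifted summits, and 3' UTRs held 1.38% against 5.65%. Summit windows were AT-rich: their mean GC content was 36.4%, against 43.9% in the windows 500 bp to the left and 42.2% in the genome. With shifted positions weighted to the GC content of the summits, coding exons held 6.56% on average and at least 5.76%, still above the observed share, and the TSS-proximal share was 22.6%. In the replicates' own top peaks coding exons held 0.580% ± 0.123 (SD, n = 3). One of the few coding summits lay in Lsp2, a gene for a larval serum protein of the fat body (arm 3L, peak 12129298 to 12129757, 135 bp downstream of the TSS, signal 190).

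**Figure D2:**
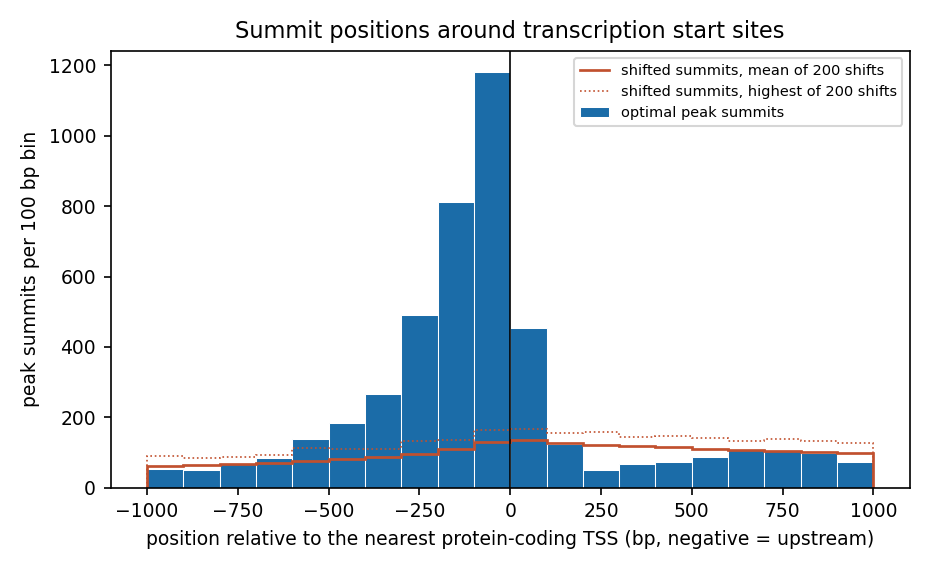
Number of optimal peak summits per 100 bp bin (bars) against the position relative to the nearest protein-coding TSS in bp, negative values being upstream; the solid line is the mean and the dotted line the highest of 200 sets of shifted summits. The bin directly upstream of the TSS holds 1182 summits against a shifted mean of 129, and the bin from 200 to 300 bp downstream holds 50 against 122.

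Several of the strongest promoter peaks lay close to the TSSs of a pair of genes. The 25 highest peaks near a protein-coding TSS and in all 3 replicates had a signal of 4647 to 10142, named 36 genes, and ranked 44 or better in every replicate. For 11 of the 25 a pair of genes had a TSS within 1000 bp, and 16 lay within 250 bp upstream of the nearest TSS. The highest stood on the X (dm6 2703636 to 2704168, signal 10142), at -29 bp from the TSS of Ugalt and -690 bp from that of eIF2Bbeta, a translation initiation factor gene. The next, of signal 9559 (3L, 19590306 to 19590879), lay at -108 bp from CG14100. The set held the mitochondrial ribosomal protein genes mRpL41 (signal 5996, beside CG8079), mRpS23 (5851, beside CenG1A) and mRpS10 (5435, beside Art3). It also held the ESCRT gene CHMP2B beside Tcs5 (6523), the eIF4E kinase gene Lk6 (6251), Chro beside Ssl1 (5719), Polycomb group gene ph-p (5200), the ecdysone-induced Sox14 (5003), and Gapdh2 of glycolysis (4647). The small heat shock gene Hsp27 had a peak of signal 5397 at -149 bp from its TSS (3L, 9383621 to 9384156), which ranked 25, 18 and 18 in the replicates. The remaining peaks named CG1888, PNPase with Gprk2, LPCAT, SLC5A11 with CG8419, CG13390 with CG17294, CG9663, CG5611 with Mtl, larp, GstE13, CG18549, Fkbp14, Tina-1, and Adf1 with Dpit47.

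All 4 genes of the insulin and FOXO pathway fixed beforehand had an optimal summit within 1000 bp of a TSS, the highest in each with a signal above the median of 321. Among all protein-coding genes 32.8% had such a summit, and 48.4% in the longest decile of gene length, which holds foxo and InR. InR, the insulin receptor gene on 3R, had 9 summits in the gene or within 1000 bp of it. Its highest (21619207 to 21619614, signal 920, rank 1202) lay at -99 bp from a TSS, and 3 of the 9 were among the top 9766 peaks of all replicates. bmm, which encodes the brummer triglyceride lipase, had 5 summits on 3L, 4 of them in the top peaks of all replicates, and the highest lay at -315 bp (14786581 to 14786887, signal 752, rank 1644). foxo itself had 5 on 3R, 3 of them in the top peaks of all replicates, and the highest lay at -243 bp in intergenic sequence (14056585 to 14056825, signal 475, rank 3144). Thor, the gene of the translation repressor 4E-BP, had 2 on 2L, the higher in a 5' UTR at -29 bp from a TSS (3478379 to 3478636, signal 451, rank 3325). The highest peak at InR ranked 585, 1881 and 2502 in replicates 1, 2 and 3, and that at Thor 2813, 4980 and 3629.

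Ribosomal protein genes and genes of lipid metabolism, carbohydrate metabolism and insulin and TOR signalling were bound more often than other genes, and olfactory and gustatory receptor genes less often. Of 13945 protein-coding genes, 4569 were bound (32.8%, 32.0 to 33.5). Of the 24 lists, 7 were bound more often and 5 less often (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted), all 12 in the same direction in 3 of 3 replicates. Ribosomal protein genes stood highest, with 70 of 87 bound (80.5%, odds ratio 8.56, exact adjusted p = 6.1e-19). They were led by RpL34b (signal 2164), RpS19b (2163), RpS27 (1859) and RpL7 (1837). The peak of RpS19b lay at -892 bp, inside an intron of another gene. In lipid metabolism 18 of 24 genes were bound (odds ratio 6.18, exact adjusted p = 1.6e-04), with Lpin, a phosphatidate phosphatase gene, at signal 3535, Hnf4 at 1086, SREBP at 1083 and Acsl at 872. In insulin and TOR signalling 22 of 32 were bound (odds ratio 4.53, exact adjusted p = 1.7e-04), led by REPTOR, a transcription factor of the TOR pathway (3326), Sesn (2704), sgg (2220) and Pi3K21B (2018). Without replicate 3 the last list no longer passed (exact adjusted p = 0.0588).

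The oxidative stress list had 15 of 22 genes bound (odds ratio 4.41, exact adjusted p = 0.00331), with Keap1 (signal 1400), GILT1 (1357), cnc (1173) and Prx4 (804). In carbohydrate metabolism 16 of 25 were bound (odds ratio 3.66, exact adjusted p = 0.00591), with Gapdh2 (4647), Eno (3207), Hex-A (1873) and Pgk (1809). The peak matched to that of Pgk by a summit within 100 bp ranked 9964 in replicate 1 but 284 and 230 in the others. Autophagy genes were bound in 15 of 24 cases (odds ratio 3.43, exact adjusted p = 0.00951), among them Atg2 (1818), Atg17 (1415), Atg18a (1154) and Atg7 (1066). Targets of FOXO named in earlier literature were bound in 13 of 21 cases (odds ratio 3.34, exact adjusted p = 0.0168), with Sesn, Atg17, InR and Hsp22 (756) highest. Binding rose with gene length, from 13.2% of genes in the shortest decile to 48.4% in the longest. Against random lists of matched length autophagy (permutation test, adjusted p = 0.0688) and the literature targets (adjusted p = 0.194) no longer passed. Autophagy did not pass in the 4883 highest peaks (exact adjusted p = 0.123), in the peaks found in all 3 replicates (0.150), or without replicate 1 (0.169) or 3 (0.110), nor did the literature targets in the 4883 highest peaks (0.0630) or without replicate 3 (0.0579).

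Olfactory and gustatory receptor genes were bound in 8 of 179 cases (4.47%, odds ratio 0.0944, exact adjusted p = 2.7e-19), the highest at Or9a (signal 749), Ir94h (695), Ir60e (460) and Gr63a (238). Of the midgut list 1 of 25 genes was bound (exact adjusted p = 0.00331), namely cad (181). Of the antimicrobial peptide genes 1 of 20 was bound, Drsl1 (234), and of the larval cuticle genes 1 of 20, Cpr49Ac (156), each with an exact adjusted p of 0.0151. Against length-matched lists neither of these passed (permutation test, adjusted p = 0.456 and 0.233), and the antimicrobial list also failed with a 2000 bp window (0.172) and without replicate 3 (0.0579). None of 111 histone genes was bound (upper Wilson bound 3.35%, exact adjusted p = 6.1e-19), and none of the 6 Hsp70 copies. Both are near-identical repeated genes to which reads may not map uniquely, so these counts are uncertain. The test also counted each copy as a separate gene. The p-value and the interval of the histone list, and its place among the lists bound less often, therefore carry little weight.

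Lists that passed in neither direction included JNK and stress kinases, with 12 of 21 bound (exact adjusted p = 0.0608), among them Atf3 (signal 2979), p38a (1690), hid (1540) and p38b (897). This list passed in the 4883 highest peaks (exact adjusted p = 0.0297), in the peaks found in all 3 replicates (0.0441), and without replicate 1 (0.00665) or 2 (0.0120). It did not pass with a 500 bp window (exact adjusted p = 0.149), a 2000 bp window (0.0833), without replicate 3 (0.0919), without the X (0.0615), or against length-matched lists (permutation test, 0.209). Mitochondrial genes were bound in 10 of 18 cases (exact adjusted p = 0.0792), with Cyt-c-p (2427), Marf (1893), blw (1351) and SdhA (905). In the full lists only replicate 1 had a summit within 100 bp of that of SdhA. An overlapping peak with its summit further away is not excluded in the others. Heat shock genes were bound in 9 of 19 cases (exact adjusted p = 0.311), among them Hsc70-5 (1434), Hsp26 (1424) and Hsp83 (1232). The unbound members of this list include Hsp70Aa, Hsp70Ab and Hsp70Ba, copies to which reads may not map uniquely. Ecdysone response genes were bound in 12 of 26 cases (exact adjusted p = 0.238), with gce (1186), Eip75B (1019), Hr3 (769) and usp (680). Insulin-like peptides and their binding proteins had 4 of 12 bound (exact adjusted p = 1): conv (797), Sdr (789), ImpL2 (298) and Ilp7 (183). Clock genes had 4 of 10 (exact adjusted p = 0.805): vri (732), cry (651), Pdp1 (513) and cwo (269). The tissue lists held 5 of 22 for muscle, led by Msp300 (2821), Zasp52 (761), Tm1 (423) and sls (346), and 3 of 11 for fat body, Adh (557), NLaz (450) and Lsp2. They further held 5 of 20 for neurons, with elav (2515), Syx1A (598), Csp (446) and Ddc (213), 2 of 11 for glue, Sgs5 (328) and Sgs1 (167), and 2 of 12 for haemocytes, crq (264) and srp (181).

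**Figure D3:**
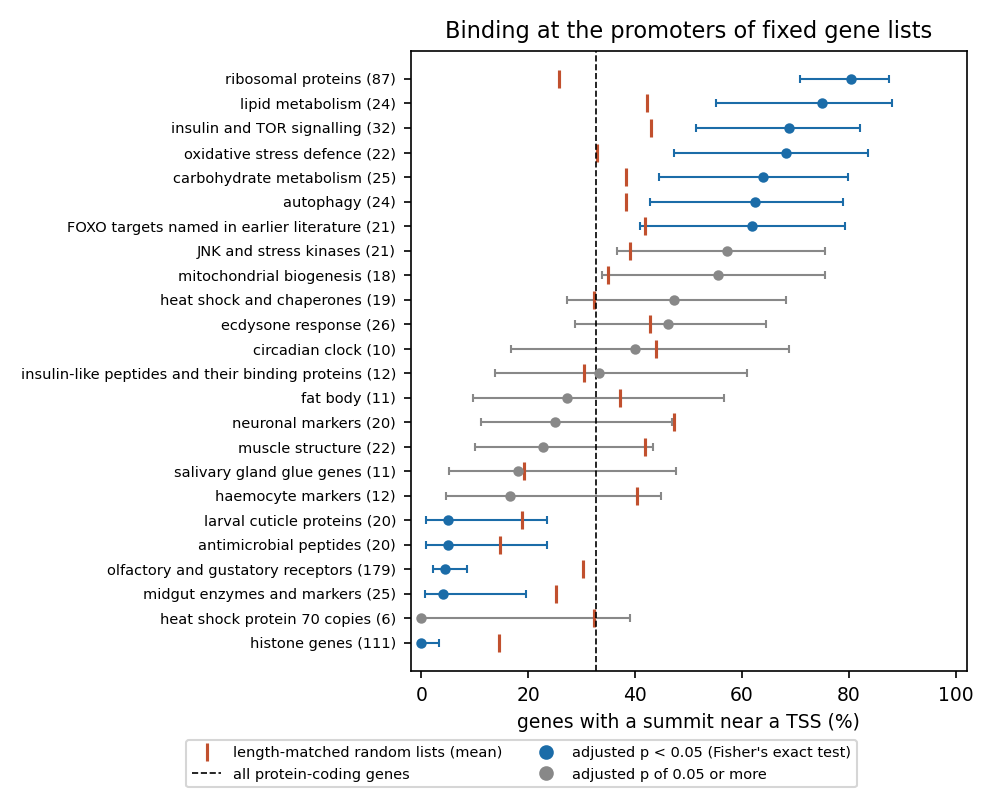
Percent of the genes of each fixed list (number of members in brackets) with an optimal summit within 1000 bp of a TSS, with Wilson 95% intervals; blue lists passed Fisher's exact test after adjustment, grey lists did not, red ticks are the mean of length-matched random lists, and the dashed line is the 32.8% of all protein-coding genes. Ribosomal protein genes stand at 80.5% and olfactory and gustatory receptor genes at 4.47%.

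Summits carried the forkhead core more often than their flanks, but no more often than flank windows of the same GC content. The core RTAAAYA, bound by forkhead proteins such as FOXO, was present at 36.8% of the summits (35.9 to 37.8), at 26.1% of the left and 26.3% of the right windows, and was found in the summit window alone at 2644 peaks and in the left window alone at 1595 (exact McNemar test, two-sided, adjusted p = 1.1e-57, higher in 3 of 3 replicates). Against GC-matched flank windows the ratio was 0.957 (95% interval 0.923 to 0.991), which turns the direction, and in the replicates' own top peaks it was 0.984 ± 0.0203 (SD, n = 3). Its ratio to the left flank, 1.41, was reached by 182 of the 210 permuted motifs, itself included. The preferred site GTAAACA was present at 5.73% of the summits and 4.65% of the left windows (adjusted p = 0.00132, exact McNemar test), with a GC-matched ratio of 1.02 (0.911 to 1.14), and of 1.14, 1.05 and 1.10 in replicates 1, 2 and 3. In the highest decile of signal the core was at 41.5% of the summits, and its GC-matched ratio was 0.953 (0.853 to 1.06).

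Motifs of broadly active promoters were the ones that stood out. The DRE (TATCGATA), the element of Dref and BEAF-32, was present at 3.05% of the summits and 0.543% of the left windows (adjusted p = 6.5e-42, exact McNemar test), with a GC-matched ratio of 3.73 (2.89 to 4.82). The Ohler 1 motif (GGTCACAC), bound by M1BP, was present at 2.32% and 0.512% (adjusted p = 1.3e-27, exact McNemar test), with a GC-matched ratio of 4.61 (3.43 to 6.18). Both were higher in 3 of 3 replicates and lay mostly near TSSs: DRE was at 5.59% of the summits within 1000 bp of a TSS and 0.417% of the others, Ohler 1 at 4.02% and 0.563%. The shares away from TSSs were close to those in the left windows of all peaks. Flank windows were matched on GC content but not on position to a TSS, so these ratios do not compare the summits with other promoters. Of the 16 motifs, 7 were higher at the summits than in the left flank and 4 were lower, and with GC-matched flanks 3 lay above 1 and 4 below by their 95% intervals. The third above 1 was GAGA (1.27, 1.11 to 1.44), which was less frequent at the summits than in the left flank without matching (4.23% and 4.90%).

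**Figure D4:**
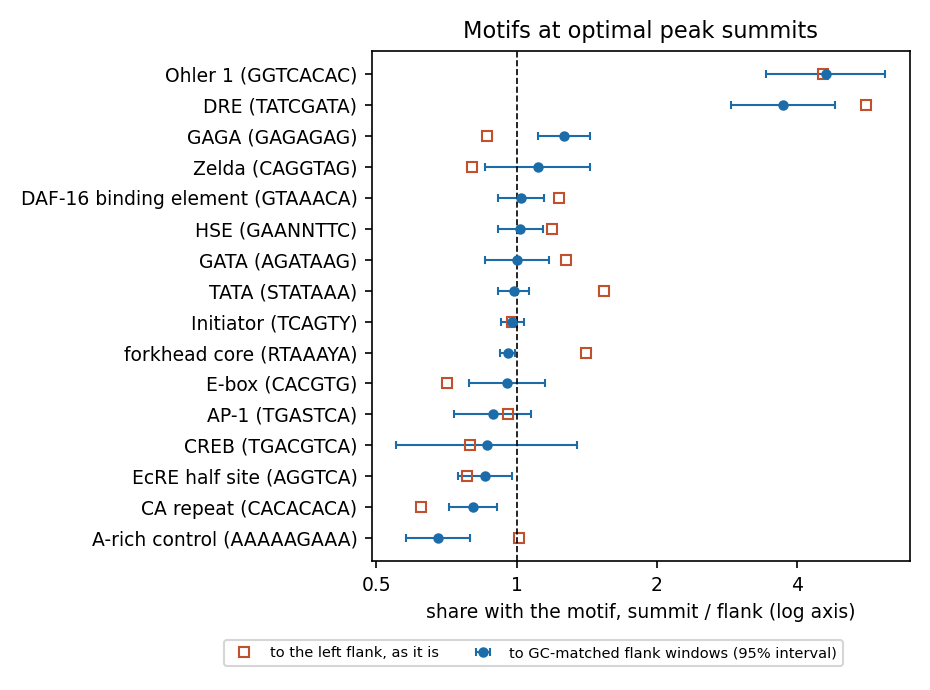
Ratio of the share of summit windows with a motif to the share of flank windows (horizontal log axis) for the 16 motifs of the panel; circles are ratios to GC-matched flank windows with 95% intervals and open squares are ratios to the left flank as it is. DRE and Ohler 1 lie at 3.73 and 4.61, and the forkhead core moves from 1.41 to 0.957 with GC matching.

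Peaks were spread over the large chromosome arms with few on chromosome 4. The X held 81.6 optimal peaks per Mb (exact Poisson 95% interval 77.9 to 85.3), 3L 75.7, 2L 74.4, 3R 71.3 and 2R 66.0, against 72.9 over all arms. Chromosome 4, largely heterochromatic, held 15 peaks or 11.1 per Mb (6.23 to 18.4). The density on the X was 1.14 times that of the large autosomal arms (1.08 to 1.19). It was 1.07 times (0.992 to 1.15) in the 4883 highest peaks, where the interval reached 1, and 1.06 times (1.00 to 1.13) without replicate 2. Of the top 9766 peaks, 19.3% lay on the X in replicate 1, 20.6% in replicate 2 and 17.4% in replicate 3. The dm3 version of the optimal list held 9415 peaks, 351 fewer than the dm6 version, with 1866 on the X and 12 on chromosome 4.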

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

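Chosen after the results were seen were the tests of arm shares in replicate 3 and of ribosomal protein genes and single-tissue genes taken apart. The design has no group that sets a biological explanation against a technical one, and no control library was analysed here.

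On dm3, 8 optimal peaks lay on scaffolds outside the main arms (5 on Uextra, 2 on 3LHet and 1 on XHet) and stood out because no comparison here used that sequence. The highest had a signal of 572.

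The forkhead core was more frequent at summits than in flanks, and summits were AT-rich. If base composition were the cause, the excess would vanish against GC-matched windows: the ratio was 0.957, and simulated AT-rich summits without any implanted core gave a raw ratio of 1.62. The tables therefore leave composition open as the whole source of the excess. The GC-matched ratio of the A-rich control was 0.679, so a ratio of 1 is not a sure baseline for such words. Whether the preferred site GTAAACA was chosen by the factor cannot be told apart from its absence, since its ratio of 1.02 had an interval on both sides of 1. In replicate 1 alone that interval lay above 1 (1.03 to 1.28), while in replicates 2 and 3 it reached below 1 (0.930 to 1.18 and 0.982 to 1.23). The ratio of GTAAACA to the left flank, 1.23, was reached by 111 of 210 permutations of its letters, itself included. A small preference for this site is therefore neither shown nor excluded.

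Replicate 3 had a smaller share of its peaks on the X, 17.4% against 19.3% and 20.6%. Replicate 3 lay below both others in 3 of 3 classes of summit GC content, with an interval above 0 in 2 of them. The lower bounds there were only 0.0465 and 0.0480 percentage points, and these intervals cover counting error only. In 1 of these 2 classes the X shares were 19.8%, 23.1% and 18.0% in replicates 1, 2 and 3. The lower share was thus seen within each class. Base composition of the library is not decided by this, since summit classes do not measure it. A lower ratio of X chromosomes to autosomes in that larval sample cannot be told apart from other sources. The fall of the X share by 12.7%, 2.24 times the largest change of an autosomal arm, restates the pattern and gives it no weight. The X shares of replicates 1 and 2 themselves differed by 6.27%, and the sexes in each mixed sample were not counted in the labels.

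Of the gene lists the ribosomal protein genes had the highest share bound. Background at very highly transcribed genes would raise all abundant transcripts, and 5 such lists together had an odds ratio of 2.40, but their parts went opposite ways, so the sum cannot be told apart from either. The glue, cuticle, fat body and muscle genes, 11 of 64 bound, had an odds ratio of 0.425 against all other genes, without matching on gene length. Beside length-matched random lists, 18.2% of glue genes were bound against 19.2%, and 5% of cuticle genes against 18.9%. For fat body it was 27.3% against 37.1%, and for muscle 22.7% against 41.9%. None of these lists passed that comparison. These genes thus showed no excess, but background at abundant genes of single tissues is not decided. Their transcription was not measured, and genes active in few nuclei could be diluted in whole larvae. Background at abundant genes used in every tissue cannot be told apart from other sources, since the 8.56 of the ribosomal protein genes (4.98 to 15.5) is itself part of the pattern. Binding of foxo at these promoters stays open as well and was not tested, since no untagged library was analysed here.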

How the results depend on the processing

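GC matching, the removal of the X, and the alternatives for arms and for the motif panel were chosen after seeing the data. The shared share of replicates was 84.1% with interval overlap, 61.3% within 50 bp, 80.2% with 4883 peaks each, 55.8% with all peaks, and 73.1% to 77.2% with 1 replicate left out. The signal correlation ranged from 0.811 to 0.848 with 1 replicate left out. The share of optimal peaks in all replicates was 75.7% with interval overlap, 49.4% within 50 bp, 35.8% with 4883 peaks, too few per replicate to match all 9766 by construction, and 87.8% with all peaks, and 71.4% to 75.8% in the 2 replicates kept when 1 was left out, where fewer lists must agree. The TSS-proximal share was 40.7% within 500 bp, 63.3% within 2000 bp, 46.9% with protein-coding TSSs, 57.2% in the 4883 highest peaks, and 50.9% to 52.8% with 1 replicate left out. Each window gave more than its highest shifted value. The density ratio of the X was 1.07 in the 4883 highest peaks, where its interval reached 1, and 1.06 to 1.18 with 1 replicate left out. The excess of the forkhead core was reversed to -1.66 percentage points with GC-matched flanks and kept its direction and its side of the threshold in the other 10 alternatives. Of the motif panel 4 motifs were higher away from TSSs and 3 with GC matching, against 7. The cause was not tested for the other moves of the replicates, the X and the panel. Of the 24 gene lists 12 were called, 8 against length-matched lists and 8 without replicate 3, and none of the 12 changed direction. The histone list, made of near-identical copies, is included in each of these counts. Unknown depth limits what absent peaks can show.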

Other observations

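Peaks away from promoters were less common among the strongest. Of the optimal summits, 4795 (49.1%) had no TSS within 1000 bp, 67.5% of these were intronic and 29.3% intergenic, but only 18 of the 100 highest peaks were among them. The highest peak of the whole list (2L, 480521 to 481442, signal 10606) lay in an intron of ush, a zinc finger cofactor of GATA factors, 1368 bp from the nearest protein-coding TSS, that of cbt. The next of this kind were in an intron of CG11050 (signal 8941), in intergenic sequence 11905 bp from CG13323 (7499), in an intron of CG32772 (6956) and in an intron of CG32486 (6446). These genes, and those that follow, were chosen after their values were seen.

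The genes with the most summits were kirre with 36 in 394149 bp, sbb with 30 in 79099 bp, Tet with 26 in 92952 bp and CG1677 with 24 in 124709 bp. In 50 sets of shifted summits the mean was 32.5 for kirre, 5.20 for sbb, 5.86 for Tet and 8.38 for CG1677, and the highest counts were 65, 23, 28 and 31. These genes were picked for their counts among all genes, so the shifted sets describe them and give no test.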
